A study of Mus musculus with 12 samples.

How the data were processed

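RNA was profiled on 12 Affymetrix mouse arrays, 3 for each of 4 groups: adipose progenitor preparations (AP) and whole adipose tissue (AT), each from inguinal subcutaneous fat (SAT) and perigonadal visceral fat (VAT). The deposited values are log2 intensities per probe set, made by the authors with the robust multi-array average (RMA) in Affymetrix Expression Console 1.3.0.187. That the log has base 2 was taken from the method and from the range of the values, 1.69 to 13.48 with 2 decimals. The labels do not state the annotation library or the level of summary of the probe sets. The values were used as deposited, without a further normalization or a filter on dim genes in the reported fit.

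The arrays held 41345 probe sets. The annotation gave 1 gene for 23521 of them, several genes for 1814 and no gene for 16010. The tests used the first kind only. Where a gene had several probe sets, as 1082 genes had, the probe set with the highest mean over all arrays was kept, which left 22180 genes. A gene without a probe set of its own in this annotation was not analysed here.

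Differences were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays and a spread shared by the groups (8 residual and 6.84 prior degrees of freedom). The fit gave 6 contrasts: AP minus AT in SAT, in VAT and averaged over both, VAT minus SAT in AP and in AT, and the interaction, which is the depot difference in AP minus that in AT. The moderated tests were 2-sided. The p-values were adjusted by the Benjamini-Hochberg method over all genes within a contrast, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are those of the moderated fit, and SD is the spread of the 3 replicates. The number of arrays limits the precision.

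Before the data were examined, 49 gene lists with 737 members in all were written down, for cell types, progenitor states, depot position, metabolism and signalling. Of the members, 663 were tested. Each list was tested with camera, which compares it with all other genes, 2-sided and with a preset correlation between genes of 0.01. The same test was run with the correlation estimated from the residuals, and with fry, whose directional test asks whether a list moves on balance and whose mixed test asks whether its genes change in either direction. The p-values were adjusted over the lists within a contrast. Members were counted both as called over all genes and as adjusted over the list alone.

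The genes named in the text follow a rule of 3 parts, also set before the data were examined. The first part takes, per contrast, up to 10 called genes with the largest rise and 10 with the largest fall whose replicates did not overlap, leaving out predicted genes, small RNA, receptors of smell and immune receptor segments. No such demand on replicates was made for the interaction. The second part is a fixed set of markers of progenitors, adipocytes, endothelium, leukocytes, mesothelium and depot position. The third part takes, per list, up to 2 called members with the largest rise and 2 with the largest fall. The levels of single genes given for the patterns weighed in the closing section were chosen after their values were seen.

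The comparisons, tests and alternatives were fixed before the data were examined. The alternatives were the replicate number as a block (fixed or random effect), empirical Bayes with trend and robust options, array weights, the arrays of the compared groups alone, quantile normalization, cyclic loess, and a shift of each array to an equal median over 13 housekeeping genes. Further ones were a filter at the 40th percentile of intensity, the mean over a gene's probe sets, all probe sets, an added demand of a log2 difference of at least 1, and leaving out each array in turn. Sample labels were also split in other ways, in all 10 ways for 3 arrays against 3 and in 100 drawn with a fixed seed for the contrasts that use all arrays.

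The code was tested on simulated data, with values drawn for the same 12 arrays. In the contrast of depots in AP, 18 of 50 genes with a true log2 difference of 0.5 were called, 47 of 50 at 1, and 50 of 50 each at 2 and 4. In that contrast 8 unchanged genes were called beside the 200 changed ones. With no gene changed, limma called 1 gene for AP against AT in VAT and 0 in each other contrast. Of 200 random gene lists 0 were called. The simulated genes were drawn independently of each other, so this does not test the list calls under correlation between genes. In the measured data, pairs of replicates differed by an SD of 0.2126 to 0.3132 on the log2 scale. Figures were drawn with Python 3.11.15. Array scans were not used here.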

Results

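Gene expression was measured on 12 Affymetrix arrays in material from C57BL/6 mice. It came from 2 fat depots, the inguinal subcutaneous depot (SAT) and the perigonadal visceral depot (VAT). From each depot, whole adipose tissue (AT) and a preparation of adipose progenitors (AP) were profiled freshly, with 3 biological replicates in each of the 4 groups. AP were prepared from the stromal vascular fraction, the cells other than adipocytes that enzymatic dissociation of the tissue releases. Beads had then removed lineage-positive blood cells and CD31-positive cells, a class that includes the endothelium. The values were log2 RMA intensities, and 22180 genes were tested. A group mean under 4.10, the 40th percentile of all probe sets, was taken as near background, and a difference against it is only a fitted value. Among the genes named here this holds for Il6, Has1, Retnla, Glb1l2, Pkhd1l1, Il1r2, Serpina3b, Otop1, Cdh9, Cdh19, H2-M9 and Ly6c1. The labels do not say which animals gave each replicate, so the p-values measure the spread between these samples, and the number of arrays limits the precision.

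The arrays fell into their 4 groups. The first principal component, with 71.2% of the variance, separated AP from AT, and the second, with 10.4%, separated SAT from VAT. The correlation across genes (which are not independent replicates) was 0.9869 to 0.9936 between arrays of 1 group. It was 0.9774 to 0.9833 between the depots within a preparation and 0.9104 to 0.9389 between the preparations. The array medians ranged from 4.49 to 4.67.

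**Figure D1:**
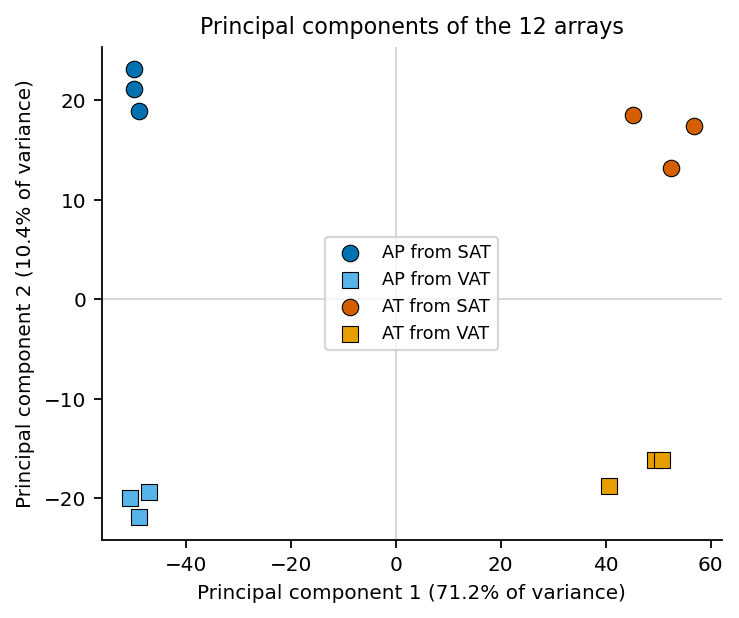
Each point is 1 array, placed by its scores on the first principal component (horizontal, 71.2% of the variance) and the second (vertical, 10.4%); circles are SAT, squares VAT, blue AP and orange AT. The 6 AP arrays lie left of 0 and the 6 AT arrays right of it, with all SAT arrays above 0 and all VAT arrays below.

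The first comparison asked which transcripts set the progenitor preparation apart from the tissue it came from. The largest rises in AP were those of immediate early and stress genes. Averaged over both depots, the immediate early transcription factor Fos (Entrez Gene 14281) was 69.6-fold higher in AP, a log2 difference of 6.12 (SE 0.098, 6 arrays per preparation). In SAT its value was 10.75 ± 0.12 (SD, n = 3) in AP and 4.64 ± 0.18 in AT. The related Fosb rose by 6.04 (SE 0.097), the zinc finger transcription factor Egr1 by 5.36 (SE 0.133) and the nuclear receptor Nr4a1 by 5.30 (SE 0.303). The inducible heat shock proteins of the 70 kDa class also rose, Hspa1b by 5.20 (SE 0.067) and Hspa1a by 5.20 (SE 0.109). So did 4 genes of inflammation and its control: the prostaglandin synthase Ptgs2 (5.29, SE 0.217), the cytokine Il6 (5.20, SE 0.139, against AT means of 3.44 and 3.66), the hyaluronan-binding protein Tnfaip6 (4.68, SE 0.132) and the mRNA-destabilising protein Zfp36 (4.44, SE 0.102). The hyaluronan synthase Has1 was among the top genes in SAT, at 5.12 (SE 0.262). All 21 measured members of the fixed list of immediate early and dissociation stress genes rose, with a median log2 difference of 4.09 (adjusted p = 5.18e-25, and adjusted p = 0.0112 with an estimated correlation).

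The largest falls in AP were those of adipocyte genes. Cidec, a protein of the adipocyte lipid droplet, fell by 6.21 on the log2 scale (SE 0.114, 73.9-fold). The hormones resistin (Retn, -6.10, SE 0.12), leptin (Lep, -5.72, SE 0.142) and adiponectin (Adipoq, -5.42, SE 0.175) fell, as did the lipid droplet protein Plin1 (-4.50, SE 0.079). The resistin-like secreted protein Retnla (-6.63, SE 0.32) and the cysteine dioxygenase Cdo1 (-6.63, SE 0.173) had the largest fitted falls, with Retnla at 3.86 in AP from VAT. Other large falls were those of the cytochrome Cyp2e1 (-6.08), the galactosyltransferase B3galt2 (-6.04), the galectin Lgals12 (-5.82), the glyceroneogenic enzyme Pck1 (-5.81) and the triglyceride-forming Dgat2 (-5.67). Haptoglobin (Hp) was among the top falls in SAT (-5.59, SE 0.198), and the galactosidase-like Glb1l2 in VAT (-5.65, SE 0.149). Of 20 mature adipocyte genes, 19 fell and Itih5 rose by 0.45 (SE 0.073); the list median was -3.37 (adjusted p = 2.63e-21).

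Metabolic gene groups fell with the adipocyte markers. All 13 genes of de novo lipogenesis were lower in AP (median -3.30, adjusted p = 7.23e-17), among them the lipogenic regulator Thrsp (-5.51) and Pnpla3 (-4.59). All 16 genes of triglyceride synthesis and lipolysis were lower (median -3.16, adjusted p = 6.06e-21). All 21 genes of oxidative phosphorylation and the citrate cycle were lower (median -1.33, adjusted p = 1.45e-17), such as Idh3a (-2.66) and Ndufs1 (-1.93); adjusted p = 0.117 with an estimated correlation. In fatty acid oxidation, 12 of 13 fell, with Acadm at -2.74 and Hadh at -2.53, while the carnitine transferase Cpt1a rose by 0.65 (adjusted p = 2.16e-08, and adjusted p = 0.117 with an estimated correlation). Of 14 brown and beige fat genes, 8 fell and 1 rose, and adjusted over the list alone 8 fell and 2 rose (adjusted p = 0.0453, and adjusted p = 0.524 with an estimated correlation). The first of these p-values was 0.05 to 0.0733 without replicate 1 of AP from SAT, 2 or 3 of AP from VAT, or 1 or 3 of AT from VAT, and 0.05 under cyclic loess. In VAT, where 2 of these genes fell and 4 rose, that list had an adjusted p of 0.975; its median of -0.04 became 0.55 when the arrays were scaled to housekeeping genes. Where no other count is given, as many members of a list passed when adjusted over the list alone.

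Markers of the depleted cell classes were lower in AP, which checks the bead depletion. The endothelial surface proteins Pecam1 (CD31) and Cdh5 fell by 2.90 (SE 0.087) and 3.64 (SE 0.142), and 14 of 16 endothelial genes fell, while the receptor kinase Tek rose by 0.90 (SE 0.17). The list median was -1.76 (adjusted p = 2.02e-11). The leukocyte antigen Ptprc fell by 2.36 (SE 0.131), the macrophage receptor Adgre1 by 3.22 (SE 0.106) and the mannose receptor Mrc1 by 4.86 (SE 0.148). All 18 macrophage and monocyte genes fell (median -3.01, adjusted p = 2.77e-18), and so did all 11 antigen presentation genes (median -0.72, adjusted p = 8.71e-07, and adjusted p = 0.136 with an estimated correlation). Lymphocyte genes had list medians nearer 0. Of 14 T and NK cell genes, 5 fell, Cd3g by 1.69 (SE 0.312) and Cd3e by 0.63 (SE 0.228, adjusted p = 0.0356). The adjusted p of Cd3e was 0.0517 to 0.0974 without any 1 AP array, replicate 1 or 2 of AT from SAT or replicate 2 of AT from VAT. The list had an adjusted p of 0.189, and of 0.0343 without replicate 3 of AT from SAT. Its median of -0.195 became 0.315 when the arrays were scaled to housekeeping genes. Of 11 B cell genes, 7 fell, Cd37 by 1.14 (SE 0.08); the median was -0.29 (adjusted p = 0.0453, and adjusted p = 0.433 with an estimated correlation), and 0.22 under the same scaling. The first of these p-values was 0.0571 to 0.0764 without replicate 1 of AP from SAT, 1 or 3 of AP from VAT, 2 of AT from SAT, or 1 or 2 of AT from VAT.

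Of 15 pericyte and smooth muscle genes, 14 rose in AP, such as the smooth muscle myosin Myh11 (3.03, SE 0.074) and the mural receptor Notch3 (2.93, SE 0.099), and Mcam fell (-1.10, SE 0.079). Their median was 1.65 (adjusted p = 9.78e-10). In the mixed list of granulocyte and mast cell genes, 5 of 13 rose, led by the mast cell proteases Tpsb2 (1.92, SE 0.137) and Mcpt4 (1.54, SE 0.154). In it 3 fell, and the adjusted p was 0.367. Of 9 Schwann cell genes, 5 rose and 1 fell (median 0.47, adjusted p = 0.147, and 0.0419 without replicate 3 of AT from SAT).

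The progenitor markers themselves rose: the platelet-derived growth factor receptors Pdgfrb by 3.16 (SE 0.149) and Pdgfra by 2.31 (SE 0.161), and the surface antigen Cd34 by 1.47 (SE 0.127). Of 17 adipose progenitor genes, 14 rose. Cd24a fell (-0.74), though it was not called when scaled to housekeeping genes, and Zfp423 fell (-0.30) but was higher by 0.22 when the arrays were scaled to housekeeping genes. The list median was 0.92 (adjusted p = 5.03e-06, and adjusted p = 0.117 with an estimated correlation). Among lists of progenitor states, 10 of 11 genes of regulatory progenitors marked by F3 rose, such as Cygb (2.89) and Gdf10 (2.78), with a median of 1.54 (adjusted p = 9.55e-09). Of 12 fibro-inflammatory genes, 11 rose, and 12 adjusted over the list alone (median 1.62, adjusted p = 7.92e-09). This list includes Il6, which rose by 5.20. Every AP sample and no AT sample was dissociated, so handling cannot be told apart from progenitor state in these rises. Of 13 genes of interstitial progenitors marked by Dpp4, 12 rose, such as Pi16 (2.67) and Cd248 (2.21); adjusted p = 8.24e-07, and adjusted p = 0.183 with an estimated correlation. Dpp4 itself rose in SAT by 1.50 (SE 0.277) and was at 0.33 (SE 0.277) in VAT, and the difference between these values did not pass (interaction adjusted p = 0.164, and 0.00364 without replicate 3 of AT from SAT). The list of committed preadipocytes marked by Icam1 split, with 7 genes higher and 5 lower; its median was 0.73 while its test pointed down (adjusted p = 0.901, and 0.0169 when scaled to housekeeping genes).

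Matrix genes moved together. All 28 extracellular matrix genes rose (median 1.61), such as fibulin 1 (Fbln1, 2.44) and tenascin XB (Tnxb, 2.22), and all 15 basement membrane genes rose (median 0.95), such as the laminins Lama2 (2.16) and Lamb2 (2.05). Both lists passed (adjusted p = 4.00e-18 and 1.73e-09), but not with an estimated correlation (adjusted p = 0.117 and 0.132). Of 22 chemokine and cytokine genes, 14 rose and Ccl8 fell (-2.40), with 17 up and 2 down adjusted over the list alone (median 1.41, adjusted p = 1.82e-07, and adjusted p = 0.0646 with an estimated correlation). This list shares Ccl2, Ccl7, Cxcl2, Cxcl10, Il6 and Il33 with the fibro-inflammatory list, so their results are not independent.

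Signalling and transcription factor genes of adipogenesis differed within each list. In the TGF-beta and BMP list, 16 of 23 rose, such as Gdf10 and the activin antagonist follistatin (Fst, 2.17, SE 0.128). Adjusted over the list alone 17 rose and 1 fell, with a median of 1.19 (adjusted p = 3.81e-08). The Wnt list had 19 of 23 genes higher and 1 lower (median 0.86, adjusted p = 1.20e-06, and adjusted p = 0.0712 with an estimated correlation), led by the secreted Wnt antagonists Sfrp1 (2.27) and Sfrp4 (1.44). Of 16 regulators that restrain adipogenesis, 12 rose and 1 fell, and 2 fell adjusted over the list alone (adjusted p = 6.46e-06, and adjusted p = 0.0636 with an estimated correlation); Id3 was at 3.13 and Klf2 at 2.43. Among 18 adipogenic transcription factors, the early factors Klf4 (3.31, SE 0.121) and Cebpd (2.76, SE 0.144) were higher and the late factors Cebpa (-3.31, SE 0.091) and Pparg (-2.18, SE 0.117) lower. In that list 9 rose and 8 fell, and 9 fell adjusted over the list alone (adjusted p = 0.723). Handling during isolation cannot be told apart from cell state in the rises of these regulators either.

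By the limma fit, 9430 of the 22180 genes differed between AP and AT over both depots, 4890 higher and 4540 lower, and 1986 of them differed at least 2-fold. Of the 49 gene lists 27 passed the camera test, and 10 of these also passed with an estimated correlation. Among the 27 was the list of sex chromosome genes, which also passed in SAT but not in VAT. Under cyclic loess its adjusted p was 0.05 over both depots and 0.0568 in SAT. Without replicate 1 of AT from SAT it was 0.0633 in SAT. Whether the sex of the animals differed between AP and AT was not tested. In SAT 7186 genes differed, 3571 higher and 3615 lower, and in VAT 7239, 3507 higher and 3732 lower. The AP and AT values did not overlap for 7059 of the genes called in SAT and 6901 of those called in VAT. Over all genes the shares without overlap were 44.6% and 41.0%, against 10% by chance for 3 against 3. Higher in both depots were 2356 genes, against 564.6 for independent calls, 2801 were lower in both (608.3), and 45 went opposite ways. Across genes, the differences in SAT and VAT had a Pearson correlation of 0.89, although genes are not independent replicates. The balance of higher and lower genes depended on the scaling. With each array shifted to an equal median over 13 housekeeping genes, the median difference of all genes moved to 0.46 in SAT, 0.62 in VAT and 0.55 over both. The genes called then rose to 16343, 18660 and 19615, of which 14675, 17439 and 17954 were higher in AP.

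**Figure D2:**
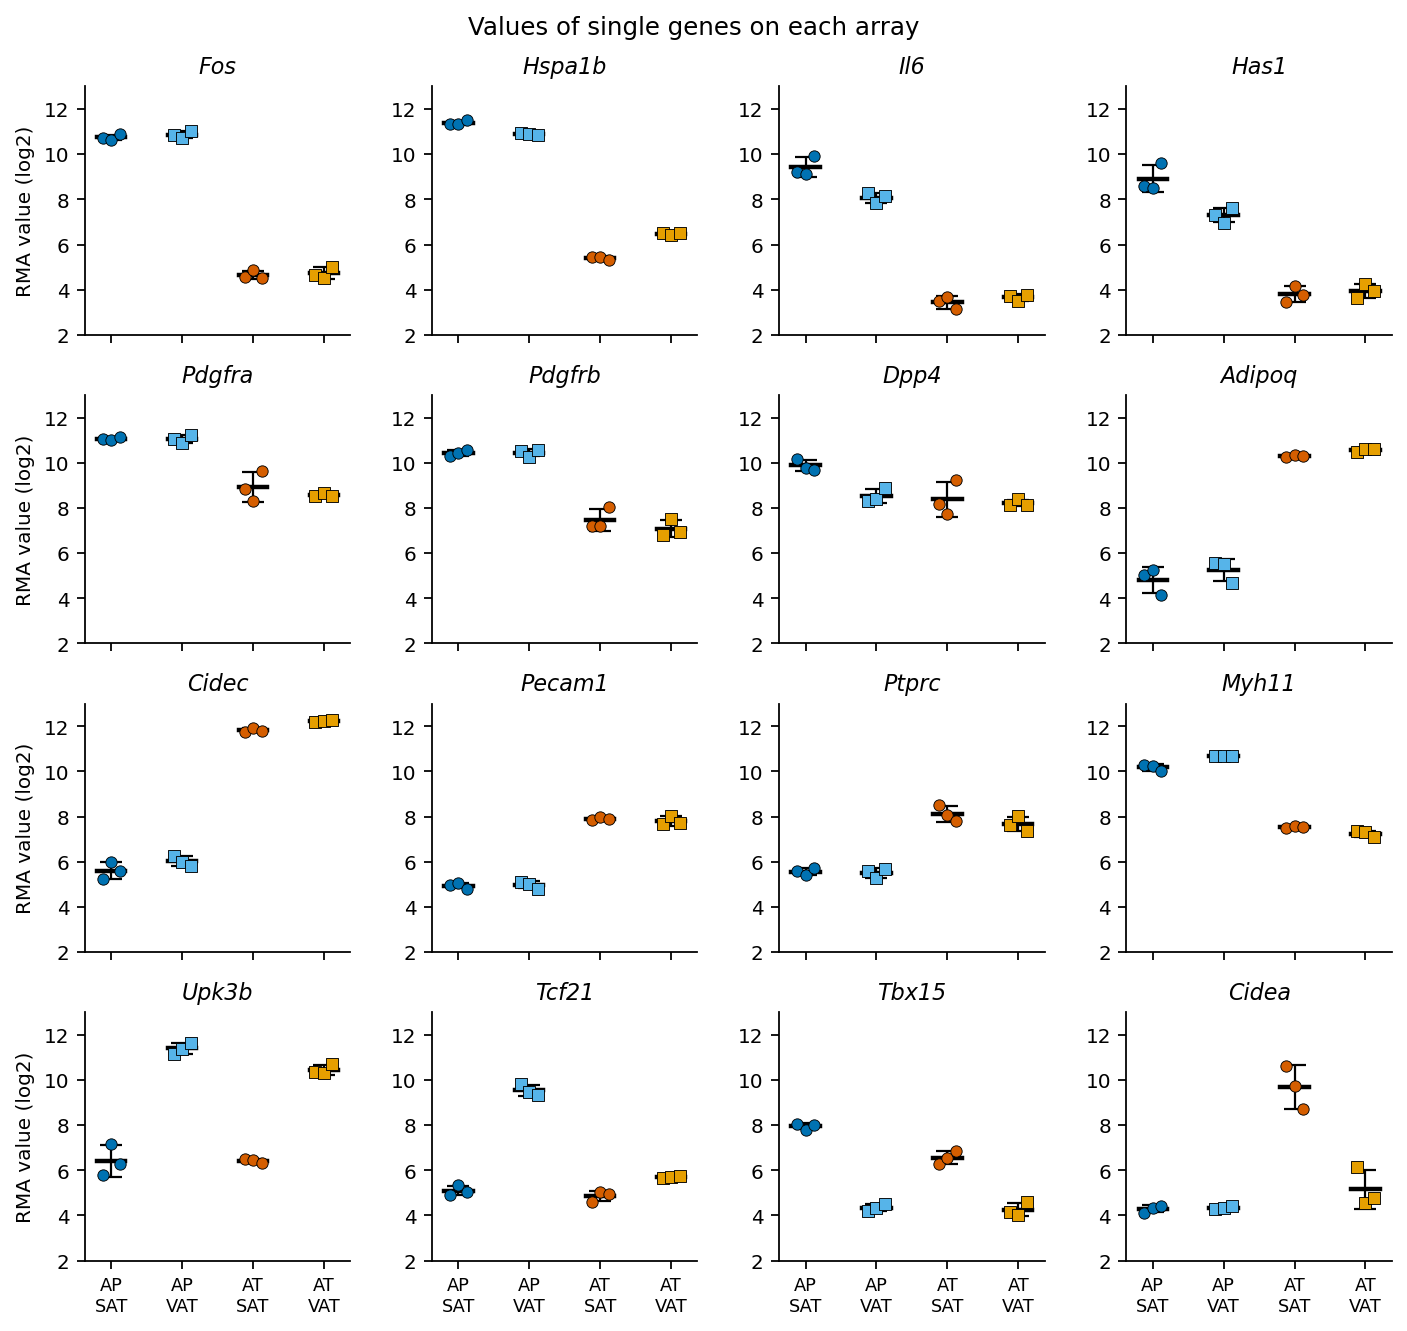
RMA values (log2, vertical axis) of 16 genes on each array, by group; points are the 3 replicates, thick lines the group mean and whiskers 1 SD. Fos lies near 10.8 in AP and near 4.7 in AT, Adipoq shows the reverse, Tcf21 is raised in AP from VAT, and Cidea in AT from SAT.

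The next comparison asked how progenitors differ between the depots. In AP from VAT, genes of the mesothelium, the epithelial lining of the body cavities, were far higher than in AP from SAT. The uroplakin Upk3b (Entrez Gene 100647) was 31.6-fold higher, at 11.40 ± 0.24 (SD, n = 3) against 6.42 ± 0.71, a log2 difference of 4.98 (SE 0.249). Upk1b (3.77), mesothelin (Msln, 3.63), Lrrn4 (3.46) and the membrane glycoprotein Gpm6a (4.48) followed. All 14 mesothelial genes were higher in VAT, with a median of 2.10 (adjusted p = 2.47e-39, and adjusted p = 0.00177 with an estimated correlation). From AT to AP within VAT, 4 of these 14 genes rose and the list median was 0.305 (adjusted p = 0.0854, and 0.0204 without replicate 1 of AP from VAT).

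Transcription factors of body position differed as well. The transcription factor Tcf21 was 4.44 (SE 0.148) higher in AP from VAT and Wt1 2.40 (SE 0.106), while the T-box factors Tbx15 (-3.61, SE 0.162) and Tbx5 (-2.76, SE 0.137) and the homeobox factor Shox2 (-1.02, SE 0.133) were lower. Of 12 genes of visceral position, 7 were higher, and 8 adjusted over the list alone (median 0.89, adjusted p = 1.05e-16). Wt1 and Bnc1 are members of the mesothelial list too, so these lists are not independent of each other. Of 10 genes of subcutaneous position, 7 were lower, such as Hoxc10 (-1.78), with a median of -0.99 (adjusted p = 4.12e-11). Across 36 HOX genes, 7 were higher, such as Hoxa5 (1.84) and Hoxa6 (0.79), and 2 lower, and 8 were higher adjusted over the list alone (adjusted p = 0.0244, and adjusted p = 0.491 with an estimated correlation). The first was 0.105 and 0.0703 without replicates 1 and 2 of AP from VAT, and 0.0588 without replicate 3 of AP from SAT. It was 0.0918 under quantile normalization, 0.118 under cyclic loess and 0.0528 when scaled to housekeeping genes.

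Other genes with large differences followed. Higher in AP from VAT were the collagen Col6a5 (4.88, SE 0.201), the fibrocystin-like Pkhd1l1 (4.13, SE 0.19), haptoglobin (Hp, 3.75, SE 0.198) and the matrix protein Cilp (3.74, SE 0.255). Lower were the decoy interleukin 1 receptor Il1r2, which fell by 6.40 (SE 0.303, 84.4-fold), the hydroxysteroid dehydrogenase Akr1c18 (-5.52, SE 0.246) and the metalloproteinase Mmp3 (-3.98, SE 0.229). The chemokines Cxcl13 (-3.22, SE 0.532) and Cxcl14 (-2.61, SE 0.206), the cadherin Cdh9 (-2.86), the alcohol dehydrogenase Adh7 (-2.71) and the class I-like H2-M9 (-2.50) were lower too.

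Some lists of progenitor states were called between the depots with the preset correlation. The lists were not tested against each other. Pdgfra and Pdgfrb had differences of -0.03 (SE 0.227, adjusted p = 0.981) and 0.01 (SE 0.211, adjusted p = 0.991). Dpp4 was lower in VAT (-1.35, SE 0.277), as were 10 of the 13 interstitial progenitor genes, 11 adjusted over the list alone. The list's largest falls were Sema3e (-2.39) and Efhd1 (-2.20), and its median was -1.35 (adjusted p = 2.07e-15, and adjusted p = 0.0832 with an estimated correlation). Of 12 fibro-inflammatory genes, 5 were lower, such as the interferon-induced chemokine Cxcl10 (-1.90) and Ly6c1 (-1.70), and 6 adjusted over the list alone (adjusted p = 8.52e-08, and adjusted p = 0.0234 with an estimated correlation). Chemokine and cytokine genes had 8 of 22 lower, with 10 lower and 2 higher adjusted over the list alone (adjusted p = 1.08e-07, and adjusted p = 0.0832 with an estimated correlation). Ccl2, Ccl7, Cxcl2, Cxcl10, Il6 and Il33 are members of the fibro-inflammatory list too, so these lists are not independent of each other. Interferon response genes had 5 of 11 lower, such as Usp18 (-2.23) and Isg15 (-1.15), and 6 adjusted over the list alone (adjusted p = 1.97e-07, and adjusted p = 0.0832 with an estimated correlation). Cholesterol synthesis genes had 5 of 13 lower, such as Insig1 (-1.09), and 9 adjusted over the list alone (adjusted p = 1.94e-07, and adjusted p = 0.201 with an estimated correlation). The regulatory list marked by F3 had 3 of 11 higher, such as matrix Gla protein (Mgp, 1.90), and 2 lower, with 7 higher adjusted over the list alone (adjusted p = 0.00549, and adjusted p = 0.181 with an estimated correlation).

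The immediate early and dissociation stress list was also called between the depots in AP, with 4 of 21 genes lower in VAT and 5 adjusted over the list alone (median -0.06, adjusted p = 0.0229, and adjusted p = 0.549 with an estimated correlation). The first of these p-values was 0.286 under quantile normalization, 0.201 under cyclic loess, 0.142 without replicate 2 of AP from VAT and 0.108 without replicate 3 of AP from SAT. The median was 0.011 under quantile normalization and 0.04 when the arrays were scaled to housekeeping genes. Outside this list, Ptgs2 (-1.42), Il6 (-1.33) and Has1 (-1.61) were lower in VAT.

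Markers of other cell types moved with depot in AP. Pericyte and smooth muscle genes had 5 of 15 higher in VAT, such as desmin (Des, 0.71), and 7 adjusted over the list alone (adjusted p = 1.25e-05). Schwann cell genes had 4 of 9 lower, such as Mbp (-0.85), and 6 adjusted over the list alone (adjusted p = 1.25e-05). Of the granulocyte and mast cell genes 4 of 13 were lower, all of them mast cell genes, such as Mcpt4 (-1.41, adjusted p = 0.000769 for the list). These 3 lists each had an adjusted p = 0.0832 with an estimated correlation. Macrophage, T cell, B cell and endothelial lists had adjusted p-values of 0.511, 0.999, 0.444 and 0.515. In all, 1250 genes differed between the depots in AP, 673 higher and 577 lower in VAT, and 370 at least 2-fold. This balance depended on the scaling and on 1 array: 811 of 1167 were higher when scaled to housekeeping genes, and 580 of 1249 without replicate 3 of AP from VAT. The values of 1247 of them did not overlap between the groups, and over all genes 20.4% did not, against 10% by chance.

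The comparison of whole tissues asked the same of AT. In AT from VAT, the serpin Serpina3b was 4.67 (SE 0.203) higher than in AT from SAT, and Pkhd1l1 (4.10), Upk3b (4.03), Upk1b (4.01), Gpm6a (3.52), Lrrn4 (3.28) and Msln (3.28) were higher. The imprinted gene Mest (3.16, SE 0.165), Wnt2b (3.13, SE 0.18) and the Wnt agonist Rspo1 (3.06, SE 0.138) were higher too, and leptin was 1.05 (SE 0.2) higher. All 14 mesothelial genes were higher (median 1.84, adjusted p = 2.95e-39). Of the 12 visceral position genes 7 were higher, and 8 adjusted over the list alone (median 0.95, adjusted p = 2.79e-13). Both lists had an adjusted p = 0.00198 with an estimated correlation.

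In AT from VAT, the beige fat gene Cidea was lower by 4.53 on the log2 scale (a difference of -4.53, SE 0.401), at 5.16 ± 0.87 (SD, n = 3) against 9.69 ± 0.97 in SAT. The respiratory chain gene Cox8b (-2.92, SE 0.299) and Otop1 (-2.55, SE 0.228) were lower with it. Of 14 brown and beige fat genes, 6 were lower in VAT, and 11 adjusted over the list alone (median -0.85, adjusted p = 3.29e-14, and adjusted p = 0.0996 with an estimated correlation). Genes of oxidative phosphorylation had 4 of 21 lower, such as Idh3a (-0.87), and 8 adjusted over the list alone (adjusted p = 4.80e-08, and adjusted p = 0.454 with an estimated correlation). In fatty acid oxidation 5 of 13 were lower, such as Acadl (-1.02), with 8 lower and 1 higher adjusted over the list alone. In de novo lipogenesis 2 of 13 were lower, with Elovl6 at -1.75 (not called with the 6 AT arrays alone), and 8 adjusted over the list alone. These 2 lists passed (adjusted p = 5.05e-06 and 8.83e-06) and each had an adjusted p = 0.355 with an estimated correlation.

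Among other falls in AT from VAT, 4 were also among the top falls in AP. Il1r2 (-4.27), Mmp3 (-3.27), Akr1c18 (-3.00) and Tbx15 (-2.30) were lower in AT too, with the interleukin receptor Il1rl2 (-2.51), apolipoprotein D (Apod, -2.20) and the Schwann cell cadherin Cdh19 (-2.06). Subcutaneous position genes had 5 of 10 lower, with 7 lower and 1 higher adjusted over the list alone (adjusted p = 4.80e-08), and Schwann cell genes 4 of 9, or 5 adjusted over the list alone (adjusted p = 1.44e-08). Both had an adjusted p = 0.0638 with an estimated correlation. Interstitial progenitor genes had 6 of 13 lower, 9 adjusted over the list alone (adjusted p = 2.47e-08, and adjusted p = 0.308 with an estimated correlation). Mast cell genes such as Cpa3 (-1.85) and Mcpt4 (-1.72) were lower, 5 of 13 in the granulocyte and mast cell list (adjusted p = 0.000708, and adjusted p = 0.126 with an estimated correlation). Macrophage genes had 2 of 18 lower, and 4 adjusted over the list alone (adjusted p = 0.00131, 0.0946 without replicate 3 of AT from SAT, and adjusted p = 0.454 with an estimated correlation). Lymphatic genes had 2 of 6 higher, and 5 adjusted over the list alone (adjusted p = 5.53e-06, and adjusted p = 0.0996 with an estimated correlation). Of the other cell type lists, the endothelial (median -0.23, adjusted p = 0.0017), T and NK cell (-0.20, 0.0198) and antigen presentation lists (-0.26, 0.011) were lower and the B cell list (0.34, 0.0238) higher. With an estimated correlation these had adjusted p = 0.355, 0.503, 0.462 and 0.454. Without single arrays they reached 0.0582 for the endothelial list (replicate 3 of AT from VAT) and 0.0672 to 0.471 for T and NK cells (replicate 1 or 2 of AT from SAT, or 1 or 3 of AT from VAT), whose list was at 0.0576 under cyclic loess. They reached 0.0672 to 0.203 for antigen presentation (replicate 1 of AT from SAT, or 1 or 3 of AT from VAT) and 0.0724 to 0.141 for B cells (replicate 1 or 3 of AT from SAT, or 1 or 2 of AT from VAT). Adjusted over the list alone, 2 endothelial and 2 antigen presentation genes were lower and 3 B cell genes higher. In all, 1009 genes differed between the depots in AT, 621 higher and 388 lower in VAT, and 251 at least 2-fold; when scaled to housekeeping genes, 393 of 871 were higher. The values of 994 of them did not overlap, against 18.1% of all genes and 10% by chance. Without replicate 1 of AT from SAT, 660 genes were called, and with the 6 AT arrays alone, 601.

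**Figure D3:**
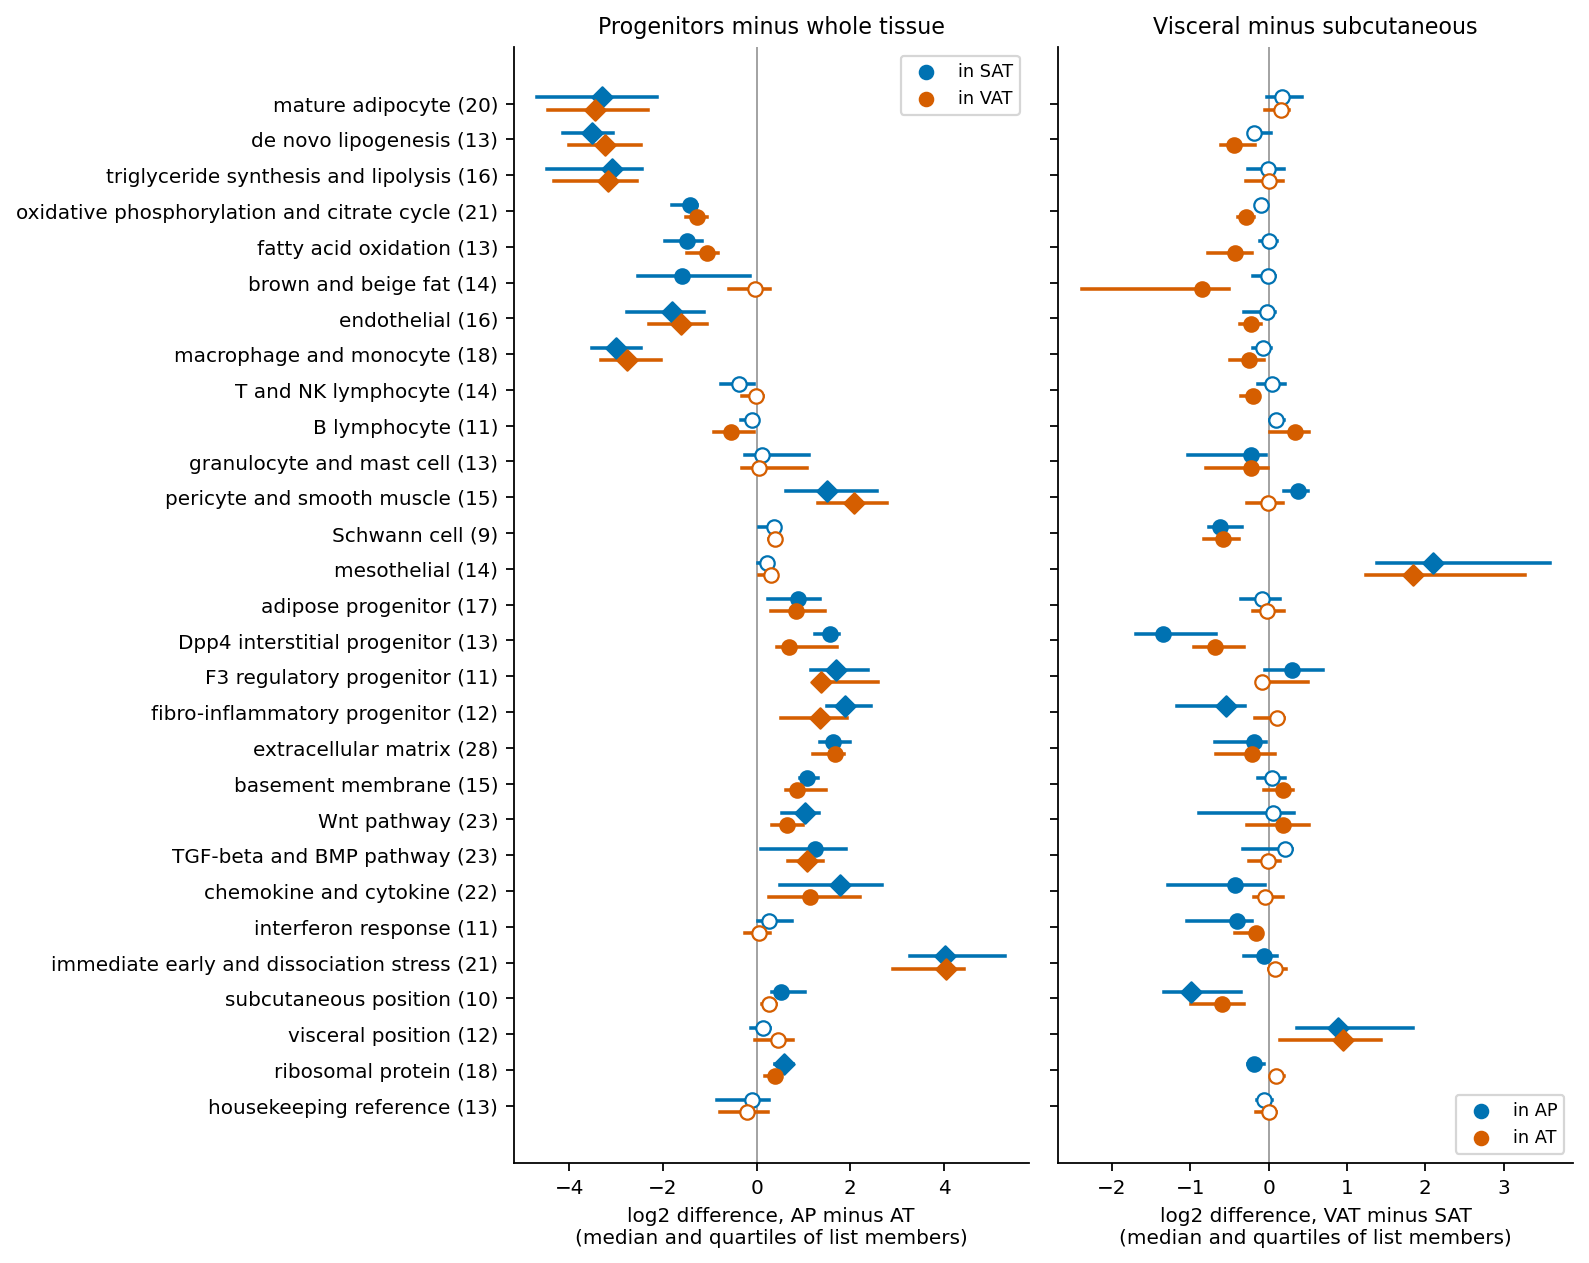
Median (symbol) and quartiles (bar) of the log2 differences of the members of 29 gene lists, with the number of members in brackets; the left panel gives AP minus AT in each depot and the right panel VAT minus SAT in each preparation. Open circles are lists with an adjusted p of 0.05 or more in the camera test, filled circles lists under it, and filled diamonds lists under it also with an estimated correlation; mesothelial genes stand out on the right at 2.10 and 1.84, and immediate early genes on the left at 4.02 and 4.05.

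The depot differences of progenitors and tissues were then set side by side. Of the genes called in each, 248 were higher in VAT in both AP and AT, against 18.8 for independent calls, and 112 were lower in both, against 10.1. A further 4 were higher in AP and lower in AT, and 17 the reverse. Of the 1250 genes called in AP, 78.2% had the same sign in AT. Across all genes the 2 differences had a Pearson correlation of 0.428 and a Spearman correlation of 0.152, and genes are not independent replicates.

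The interaction tested whether the depot difference in AP departed from that in AT. Tcf21 had the depot difference of 4.44 in AP and of 0.85 (SE 0.148) in AT, an interaction of 3.60 (SE 0.21, adjusted p = 7.64e-07). Hp followed, with an interaction of 3.42 (SE 0.28), and its value in AP from SAT, 6.11 ± 0.49 (SD, n = 3), lay below the other groups. Col6a5 (2.23, SE 0.284), the neurotrophin receptor Ntrk3 (2.76, SE 0.266) and the matrilin Matn2 (2.08, SE 0.161) also had positive interactions. Cidea (4.58, SE 0.567) and Otop1 (2.81, SE 0.323) had positive interactions with depot differences in AT. In AP, Cidea was at 4.30 in SAT and 4.34 in VAT, and Otop1 at 3.93 and 4.20. Brown and beige fat genes as a list had a median interaction of 0.96, with 2 of 14 called and 6 adjusted over the list alone (adjusted p = 2.35e-09, and adjusted p = 0.235 with an estimated correlation).

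Negative interactions were led by Serpina3b (-4.66, SE 0.287), whose value was 8.11 ± 0.55 (SD, n = 3) in AT from VAT and between 3.35 and 3.44 in the other groups. The lubricating proteoglycan Prg4 (-4.36, SE 0.642), Cxcl13 (-3.73, SE 0.752), Mest (-2.55, SE 0.233), Akr1c18 (-2.52, SE 0.348), and Tbx15 (-1.30, SE 0.23) followed, as did Il1r2 (-2.13, SE 0.428), whose adjusted p of 0.0169 became 0.0512 without replicate 1 of AP from SAT. Il6 (-1.56), Cxcl10 (-1.73) and Hspa1b (-1.56) were among them as well, so the rise of each from AT to AP was smaller in VAT. Complement genes had 3 of 13 called lower, such as C6 (-2.01) and C4b (-1.96), with 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.235 with an estimated correlation). Without replicate 1 or 2 of AT from SAT the first was 0.0564 or 0.0697, and under cyclic loess 0.0564. In all, 476 genes were called in the interaction, 219 positive and 257 negative, and 284 of them were among the genes called for depot in AP. Positive were 270 of 477 under cyclic loess, 258 of 506 under quantile normalization and 356 of 483 when scaled to housekeeping genes. The count depended on single arrays: it was 264 without replicate 1 and 309 without replicate 2 of AP from SAT, 279 without replicate 2 of AP from VAT and 293 without replicate 1 of AT from SAT.

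**Figure D4:**
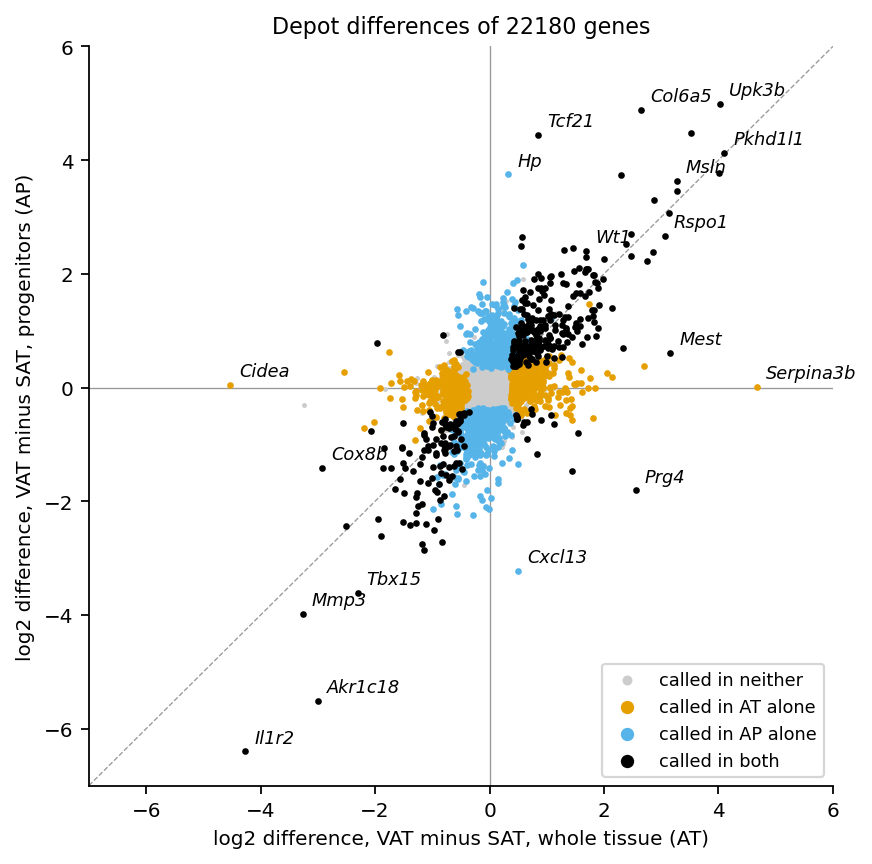
Log2 difference between VAT and SAT of each of the 22180 genes in AT (horizontal) and AP (vertical); the dashed line marks equal differences, and colours show in which preparation the adjusted p was under 0.05. Pkhd1l1 lies on the diagonal, Upk3b at the upper right and Il1r2, below the diagonal, at the lower left, Tcf21 and Hp are raised mainly in AP, and Serpina3b and Cidea lie near 0 on the vertical axis.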

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

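The tests of purification, of handling, of mesothelial and progenitor sources and of mural and mast cells were chosen after the results were seen, and the test of normalization and the splits of the samples before.

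The interaction called 476 genes, whose fitted depot difference in AP departed from that in AT. AP and AT differ in their cells. The interaction therefore cannot tell a changed depot effect within cells from a changed share of those cells, which was not tested. Tbx15, Akr1c18 and Il1r2, for example, had low intensities in both VAT groups. Their negative values reflect mainly the higher intensity in AP than in AT from SAT. Each value below is the log2 depot difference in AP minus that in AT and passed the interaction test in limma. Besides Cidea (4.58), Tcf21 (3.60), Hp (3.42), Otop1 (2.81), Ntrk3 (2.76), Col6a5 (2.23) and Matn2 (2.08), positive values were found for Pdk4 (2.38), Lrrn1 (1.97), Kdr (1.95), Apod (1.48), Cdh19 (1.3), Inhbb (1.27), Mgp (1.12), Myh11 (0.79) and Wt1 (0.71). Negative values were found for Serpina3b (-4.66), Prg4 (-4.36), Cxcl13 (-3.73), Mest (-2.55), Akr1c18 (-2.52), Rasl11b (-2.34), Folh1 (-2.34), Agt (-2.33), Ednrb (-2.14), Il1r2 (-2.13), C6 (-2.01), C4b (-1.96) and Adh7 (-1.88). Smaller ones were those of Has1 (-1.76), Cxcl10 (-1.73), Cdh9 (-1.70), Usp18 (-1.67), Tbx5 (-1.57), Il6 (-1.56), Hspa1b (-1.56), H2-M9 (-1.53), Tbx15 (-1.30), Fzd4 (-0.94), Isg15 (-0.88) and Wnt2 (-0.86). Some calls were lost without single arrays. The adjusted p of Wt1 was then 0.0501 to 0.0671 (without replicate 1 of any group, or replicate 2 of AP from VAT) and that of Isg15 0.0575 to 0.063 (replicate 1 or 2 of AP from SAT, 2 of AP from VAT or 1 of AT from SAT). That of Mgp was 0.0562 to 0.0856 (replicate 1 or 2 of AP or of AT from SAT, 2 or 3 of AP from VAT, or 1 of AT from VAT), and that of Wnt2 0.0568 to 0.0711 (replicate 1 or 2 of AP from SAT, 1 of AT from SAT or 3 of AT from VAT).

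As lists, 17 passed the interaction test with the preset correlation and 0 with the estimated one, while 8 passed the directional fry test and 32 its mixed test. Positive median interactions were those of brown and beige fat (0.963), fatty acid oxidation (0.463), pericyte and smooth muscle (0.32), cell cycle (0.293) and oxidative phosphorylation genes (0.177). Negative ones were those of interstitial progenitor (-0.823), lymphatic (-0.672), fibro-inflammatory (-0.572), chemokine and cytokine (-0.47), senescence (-0.462), cholesterol synthesis (-0.453), Wnt (-0.347), interferon response (-0.337), ribosomal (-0.308), subcutaneous position (-0.243), complement (-0.227) and immediate early genes (-0.133). Under the housekeeping shift the last median became 0.0267 and under cyclic loess 0.0151, where the immediate early list (adjusted p = 0.149) and the complement list (0.0564) lost the preset call. Without replicate 1 of AT from SAT, 4 lists lost the preset call: oxidative phosphorylation (adjusted p = 0.247), Wnt (0.054), subcutaneous position (0.0624) and complement (0.0564). Without replicate 2 of AT from SAT complement lost it as well (0.0697), and subcutaneous position without replicate 1 of AP from SAT (0.0715), replicate 3 of AP from VAT (0.0537) or replicate 3 of AT from VAT (0.0784).

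Probe sets paired with no gene or with several were outside the comparisons, 17824 in all. When all probe sets were tested together, 2367 of them were called for AP against AT in SAT, 2366 in VAT and 3717 over both depots. For VAT against SAT 161 were called in AP and 318 in AT, and 68 in the interaction.

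For 3 arrays against 3, the 10 possible splits are too few for a share under 0.05. The real split (1 of 10 in each case) called 7186 genes for AP against AT in SAT and 7239 in VAT, and the highest other split 0 in each. For the depots it called 1250 genes in AP, with 0 in the highest other split, and 1009 in AT, with 7. Over both depots, the real split was the only 1 of 100 that called as many as 9430 genes, and the highest other split called 2740. That share is the lowest that 100 splits can give. Most other splits mix AP and AT arrays within a group, which widens the spread and lowers their counts, so this comparison does not exclude chance. For the interaction, 2 of 100 splits called as many as the real 476. These splits mix the depots within each preparation, so they remove the depot differences along with the interaction. They therefore cannot exclude chance for the interaction alone. The highest other split called 1677 genes; it is the one in which the depot labels of AT are turned, which measures the sum of the depot differences and so reflects a structure of the samples.

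Intensities of different probe sets do not rank transcripts, so the levels given for the patterns below show only that the genes were detected.

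The first pattern weighed is the rise of immediate early genes in AP, by a median of 4.09 over 21 genes. All of them had group means in AT at or above the 40th percentile of intensity. The choice among the scalings tried does not account for it, since the lowest median under 3 other scalings was 4.08. The RMA values were already normalized, so quantile normalization (4.08) and cyclic loess (4.12) could change them little. The housekeeping shift gave 4.6. Of the 21 genes, 12 rose by more than Pdgfrb, beyond 2 standard errors on each side. Pdgfrb was the progenitor marker with the largest rise over both depots (3.16, SE 0.149). Enrichment by the factor of that marker does not account for these 12. The rise of 1 marker is no upper limit, so enrichment of progenitors cannot be excluded. In VAT the marker Tcf21 rose by 3.84 (SE 0.148) and Pdgfrb by 3.36 (SE 0.211). Handling during isolation, which every AP sample had and no AT sample had, may be the source, but the median of 4.09 cannot be told apart from other differences between the preparations, since handling and preparation coincide in these groups. A biological difference between AP and AT stays open as well, and one other than enrichment was not tested.

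The second pattern is the mesothelial difference between the depots. All 14 genes were called higher in VAT in both AP and AT, the 4 keratins included, which is consistent with mesothelial cells in the VAT samples; the members with the highest intensities, Upk3b and Gpm6a, were at 11.40 and 9.72 in AP and 10.46 and 9.36 in AT from VAT. The beads against blood lineages and CD31 would not remove such cells. Of these genes, 13 had a group mean in AP from SAT at or above the 40th percentile. Another list holds 3 of them, Wt1, Bnc1 and Aldh1a2. Progenitors as the only source stay open too. The list's median from AT to AP in VAT, 0.305, was not below the lower quartile of the progenitor list (0.30). Pdgfra and Pdgfrb rose there by more, 2.47 (SE 0.227) and 3.36 (SE 0.211). Over both depots Pdgfrb had the largest rise of the progenitor list, while Cd24a and Zfp423 fell, so single markers do not decide the question.

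The third pattern is the rise of mural and mast cell genes in AP. Removal of adipocytes alone would raise every other class. The endothelial and macrophage medians over both depots were at most -1.76, but the beads had depleted these classes. Their falls therefore cannot decide whether the removal of adipocytes raised the mural and mast cell genes. At least 12 of 15 mural genes rose in each depot, as they would if the depletion kept mural cells. The members with the highest intensities, Acta2 and Myh11, were at 11.39 and 10.19 in AP from SAT. In AP from VAT they were at 11.72 and 10.68. All 15 genes had group means in AT at or above the 40th percentile, and no other list holds them. Of 6 mast cell genes, 4 rose in SAT and 5 in VAT. Mast cells kept by the depletion may be a source if the lineage beads lacked an antibody to them. The members with the highest intensities, Cpa3 and Tpsb2, were at 10.36 and 8.94 in AP from SAT. In AP from VAT they were at 9.30 and 7.91. In AT from each depot, 5 of the 6 had group means at or above the 40th percentile. Progenitors that express mural genes stay open and were not tested.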

How the results depend on the processing

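All alternatives were chosen before the data were examined. The counts of called genes stayed within 1.5 times the reported ones under empirical Bayes with trend and robust options, array weights, quantile normalization, cyclic loess, the 40th percentile filter and the mean of all probe sets. The exceptions were as follows. The housekeeping shift moved the counts to 16343 in SAT, 18660 in VAT and 19615 over both for AP against AT, since it moves all AP values up: the median difference of all genes became 0.46, 0.623 and 0.545. It became 0.1 for the depots in AP, -0.0567 in AT and 0.157 in the interaction. A demand of a log2 difference of at least 1 left 2204, 1966 and 1986 genes for AP against AT, 370 and 251 for the depots in AP and AT, 221 in the interaction and 112 shared by the depot contrasts; by construction it can only remove genes. With the arrays of the compared groups alone 601 genes were called between the depots in AT, with fewer samples in the fit. Signal over background limits the dim genes: with those at or above the 40th percentile, an intensity of 4.10, 7091, 7068 and 9008 genes were called for AP against AT. With all probe sets the interaction called 281; the cause was not tested.

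Leaving out single arrays gave 6110 to 7341 genes for AP against AT in SAT, 6027 to 7432 in VAT, 8623 to 9644 over both, 849 to 1374 for the depots in AP and 279 to 345 shared. The range was 660 to 1026 for the depots in AT, with 660 without replicate 1 of AT from SAT. In the interaction it was 264 to 626: 264 without replicate 1 and 309 without replicate 2 of AP from SAT, 279 without replicate 2 of AP from VAT, 293 without replicate 1 of AT from SAT, and 626 without replicate 3 of AT from SAT. Fewer samples account for lower counts in part, and the cause of the rise was not tested. Replicate 3 of AT from SAT stood apart from replicates 1 and 2 in some genes. On it Pdgfra was at 9.64 against 8.82 and 8.31, and Dpp4 at 9.23 against 8.19 and 7.73. Cidea was at 8.71 against 10.64 and 9.73, while Adipoq was alike, at 10.32 against 10.27 and 10.36.

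For the gene lists, the preset correlation passed 26 lists in SAT, 25 in VAT and 27 over both, 19 and 23 for the depots in AP and AT, and 17 in the interaction. With an estimated correlation 13, 10, 10, 4, 2 and 0 passed. The directional fry test passed 38 lists in VAT, 42 over both, 11 for the depots in AT and 8 in the interaction, and its mixed test 46, 45, 48, 37, 37 and 32; these tests ask another question. The other scalings left the numbers of lists within 1.5 times. Leaving out single arrays moved the lists of the depots in AT to between 15 (without replicate 3 of AT from VAT) and 25; the cause was not tested.

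Reversed under the housekeeping shift were, in SAT, Fzd4 (0.10), Il1rn (0.03) and Mdm2 (0.03), in VAT Mdm2 (0.27) and Zfp423 (0.02), and over both Cdh19 (0.05), Hoxa4 (0.14), Mdm2 (0.15), Trp63 (0.13) and Zfp423 (0.22), all small falls that the shift of all genes carried over 0. A change of sign where neither fit called the gene is counted as unchanged. Of the called genes followed through every alternative, 126 of 148 kept the call in SAT, 121 of 143 in VAT, 134 of 154 over both, 81 of 105 and 64 of 95 for the depots in AP and AT, and 33 of 64 in the interaction.

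With the replicate block as a fixed effect 7013, 6968, 9169, 1187, 946 and 417 genes were called in the 6 contrasts, of which 6902, 6868, 9056, 1127, 899 and 383 were shared with the reported fit, and the random block had a correlation of -0.0592. Over 18 pairs of arrays with the same number the correlation of residuals was -0.28 to 0.159, 3 above 0.1. The best match had the same number in 14 of 36 cases. These values show no strong pairing by number. They cannot tell whether samples with the same number shared animals, which the labels do not state.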

Other observations

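These values belong to gene lists outside the main comparisons; no explanation was tested for them. Over both depots, 16 of 18 ribosomal protein genes were higher in AP (median 0.431, adjusted p = 2.16e-06, and adjusted p = 0.0712 with an estimated correlation). Of 24 paracrine growth factors 10 rose and 10 fell, or 14 and 4 under the housekeeping shift (adjusted p = 0.914), with Vegfd at 1.40 and Fgf7 at 1.38, and Nrg4 at -2.12 and Vegfb at -2.02. Of 13 complement genes 5 rose and 4 fell, or 9 and 2 under that shift (adjusted p = 0.476), such as C7 (2.46) and Cd59a (-2.33). Of 13 genes of insulin signalling and glucose uptake 4 rose and 8 fell, or 5 and 5 under that shift, such as Irs2 (1.85) and Slc2a4 (-1.95), with an adjusted p of 0.0526 that became 0.0386 without replicate 3 of AP from VAT, 0.0407 without replicate 1 of AT from SAT and 0.00193 under the housekeeping shift. Of 15 hypoxia and glycolysis genes 4 rose, such as Adm (2.40), and 10 fell, such as Bnip3 (-3.24), with an adjusted p of 0.028, 0.0539 under cyclic loess and 0.342 with an estimated correlation; under the housekeeping shift 6 rose and 5 fell. Each of the counts without the shift was equal when adjusted over the list alone.

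Between the depots, 10 of 23 Wnt pathway genes differed in AP, 4 higher and 6 lower in VAT, and adjusted over the list alone 6 were higher and 7 lower (adjusted p = 0.908). Among them were Rspo1 (2.67), Sfrp1 (1.81), Dkk2 (-2.14) and Wnt2 (-1.81). The TGF-beta and BMP list had 4 higher and 4 lower, 5 each adjusted over the list alone (adjusted p = 0.303), with Inhbb at 1.50 and Bmp7 at -1.58. Of 28 extracellular matrix genes 1 was higher and 9 lower in AP from VAT, 3 and 10 adjusted over the list alone (adjusted p = 0.000276, and adjusted p = 0.698 with an estimated correlation). The retinaldehyde dehydrogenases Aldh1a2 (1.67 in AP and 1.58 in AT) and Aldh1a1 (1.21 and 1.57) were higher in VAT.

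The housekeeping list, which sets the shift of the arrays, itself held 5 genes higher and 6 lower in AP over both depots (median -0.1, adjusted p = 0.116, and 0.0202 after the shift). For VAT against SAT in AP, 1 of 14 skeletal muscle genes, 1 of 8 epididymis genes and 3 of 9 ovary and uterus genes were called, against 5.64% of all genes. Their camera tests had adjusted p-values of 0.625, 0.951 and 0.672, and the counts were equal when adjusted over the list alone.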
